A study of Arabidopsis thaliana and Zea mays subsp. mays with 14 samples.

How the data were processed

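ATAC-seq libraries were made from nuclei of 7-day-old Arabidopsis seedlings or roots, grown for 7 to 8 days with 16 hours of light. Per the labels' protocols, fresh tissue was chopped, nuclei were enriched on a density gradient and sorted, Tn5 was applied to 50000 or 500 nuclei, and libraries took 10 to 13 PCR cycles. The same protocol text stands with every sample, the crude nuclei included. Of 14 samples, 10 had a list of called regions and formed 5 groups of 2. The other 4 (both samples named genomic DNA, the maize sample and a further seedling sample named by a number of reads) were not analysed here, so no background from genomic DNA is given. The labels do not say whether libraries of a group came from separate plants.

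Each list gave chromosome, start, end and a score per region. The score is the authors' own value for a region; its definition, the peak caller and the caller's settings are not given in the sources used here. It served only to rank regions within a library. The regions were used as the authors called them in each library. The genome build is TAIR10 per the submitters' processing notes. No read counts were in the lists, so the depth is unknown and no interval from read counts is given.

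Genes came from the RefSeq annotation of TAIR10.1, joined to the lists by position, on the ground that the nuclear chromosomes of both versions hold the same sequence. This was checked on sorted seedling replicate 1. In 112 of 112 windows of 1 Mb with at least 50 genes, regions covered gene ends more often than positions 5000 bp away. The table held no strand, so each protein-coding gene took a window at both ends, 1000 bp outside to 200 bp inside, up to 2400 bases, where the design had named a window at the start alone. The table held no exons, so exons, introns and untranslated regions were not separated. No genome sequence was used here, so the planned motif test was not run. All regions lay on the 5 nuclear chromosomes, so the alternative that adds other chromosomes moved nothing.

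Covered bases per gene were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust), with all 10 libraries in the fit so that groups shared an estimate of spread. The 23893 genes covered in at least 2 libraries were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Root, crude, 500 nuclei and H2AX-GFP were each set against the sorted seedling group, and root against the mean of the 4 seedling groups. These comparisons share the sorted seedling libraries and are not independent. The procedure was tested on simulated data. There, changed genes were set to no covered base in both root libraries or in all seedling libraries. For root against sorted seedlings it recovered 26% of such genes with a mean level of 400 to 800 bases and 82% at 1600 to 2000. Of 120 calls, 7 lay outside the changed genes. Partial differences were not simulated, so the recovery of those is unknown.

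The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The 11 lists held 306 genes, all matched by locus tag. A list was compared with all other tested genes by Fisher's exact test (two-sided, adjusted over 22 tests per comparison). Genes with overlapping windows are not independent, so counts of separate loci are given for all called genes, though not for the lists. For root against sorted seedlings, the rule named up to 15 called list genes per direction, by the largest difference. It also named 5 other called genes per direction, covered in both libraries of a group and at 0 in both of the other. The other comparisons took up to 5 of each kind, and HTA3 and HTA5 were always given for H2AX-GFP.

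Regions of all libraries were merged where they touched or overlapped, and counted as called in a library if 1 base was covered. Library pairs were compared by the Jaccard index, with exact permutation tests over divisions of the libraries. With 2 libraries against 2 no p under 0.33 can be reached. Alternatives were other windows, quantile normalization, division by covered length, the better-scoring 50% of regions, the same number of regions per library, other filters and fits, a replicate block, and each library left out in turn. The gene span window, each gene end on its own, leaving out libraries of groups outside a comparison, replicate numbers within groups, further settings for the lists, list means per library and gene families were chosen after the data had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.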

Results

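Open chromatin of Arabidopsis thaliana was profiled by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into accessible DNA. Nuclei were purified by fluorescence-activated nuclei sorting. The 10 libraries analysed here formed 5 groups of 2. The reference group held 50000 sorted nuclei from whole seedlings of the wild-type accession Col-0. The others were 500 sorted nuclei from such seedlings, 50000 sorted root nuclei, 50000 seedling nuclei labelled as crude (the protocol text names sorting for every sample, so how these were purified is not given in the sources used here), and 50000 nuclei from seedlings with a 35S:H2AX-GFP transgene, which makes a green fluorescent histone variant H2AX. The plants were 7 days old. Each library came with its own list of called regions, which counted between 22138 and 29309 and covered between 13.78 and 24.61 Mb, or 11.57% to 20.66% of the 5 nuclear chromosomes. The lists carried no read counts, so the depth behind each region is unknown. Nothing in the labels says that the libraries of a group came from separate cultures. P-values from limma and from permuting libraries thus measure the spread between these libraries, which may be technical. Fisher's exact tests and the permutation over genes take each gene as a unit, neighbours that share a region included, and measure no such spread.

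Where the regions lay was compared with gene positions, since the title of the series names the discovery of cis-regulatory regions. Sequence outside protein-coding genes but within 1000 bp of a gene end made up 19.77% of the chromosomes and held 35.36% to 48.91% of the region midpoints of a library, a ratio of 1.788 to 2.474. Spans of protein-coding genes held 0.656 to 0.952 times their share of the chromosomes. Pseudogene spans, 8.68% of the chromosomes, held 0.071 to 0.13 times theirs, and the rest of the chromosomes 0.701 to 0.861 times. At the annotated gene ends themselves, 31.03% to 50.03% of positions were covered, against 6.97% to 18.95% at 500 bp inside a gene. The ratio near gene ends was above 1 in each of the 10 libraries, also by bases and with a flank of 500 bp. By bases, the gene span ratio of crude replicate 1 was 1.022, and with the 500 bp flank the ratio elsewhere was 1.001 to 1.009 in 4 libraries. The ratio near gene ends in sorted seedling nuclei was 2.425 ± 0.041 (SD, n = 2) and in root nuclei 2.325 ± 0.143 (SD, n = 2), a gap smaller than the root SD.

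Roots were compared with whole seedlings at the same number of sorted nuclei, to ask which regulatory regions differ between tissues. Genes of photosynthesis had fewer bases covered by called regions in roots. The value given is the number of covered bases within 1000 bp outside to 200 bp inside both ends of a gene. RBCS2B (AT5G38420) and RBCS1B (AT5G38430), neighbouring genes for the small subunit of Rubisco, had 2223 ± 142 and 1761 ± 96.2 covered bases of at most 2400 in sorted seedlings (SD, n = 2) and no covered base in either root library. How reads shared by such related copies were placed is not given in the sources used here. Of the other small subunit genes on the list, RBCS1A had 2400 bases in sorted seedlings and 1752.5 ± 682.4 in roots (limma, adjusted p = 0.509). RBCS3B had 1735 ± 575.6 and none in roots (SD, n = 2 each), and was not called either (limma, adjusted p = 0.0607). LHCB2.2 (AT2G05070), an antenna protein of photosystem II, had 1809 ± 278 in seedlings, and its window, which overlaps that of the called gene AT2G05060, was covered in 1 of the 2 root libraries. PSAL (AT4G12800), a subunit of photosystem I, had 1578 ± 252 and 315 ± 50.9, and GLK1 (AT2G20570), a transcription factor of chloroplast development, 1412 ± 186 and 26.5 ± 33.2 (SD, n = 2 each). In the opposite direction, BHLH38 (AT3G56970), a transcription factor of the iron deficiency response, had 1131 ± 98.3 covered bases in roots, and PHO1 (AT3G23430), which loads phosphate into the xylem, 523 ± 103 (SD, n = 2 each), with no covered base in either sorted seedling library.

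Of 45 photosynthesis genes tested, 5 fell in roots and none rose, and 30 fell when the p-values were adjusted over the list alone. The share exceeded that of other genes (Fisher's exact test, adjusted p = 1.33e-04), and 44 of the 45 had fewer covered bases in roots (median difference -885 bases, against -83 over all genes). Genes of the cuticle and shoot epidermis followed, with 3 of 15 lower (Fisher's exact test, adjusted p = 8.97e-04) and 6 adjusted over the list alone (median difference -899 bases, 14 lower). These were KCS6 (AT1G68530, with the called neighbours BBX14 and AT1G68526), an elongase for wax precursors, with 1774 ± 62.9 bases in seedlings and none in roots, BDG1 (AT1G64670), needed for the cuticle, with 1476 ± 390 and none, and FDH (AT2G26250), another fatty acid elongase of the epidermis, with 1281 ± 230 and 144 ± 40.3 (SD, n = 2 each). The cuticle list no longer passed with a replicate block, with the 500 bp window, after division by covered length or without either crude library. The photosynthesis list passed with the block and that window (Fisher's exact test, adjusted p = 6.36e-08 with the block), but not after that division or without either H2AX-GFP library. Among genes of root nutrient uptake, BHLH38 and PHO1 were the 2 of 28 that rose (Fisher's exact test, adjusted p = 2.87e-03), with 3 adjusted over the list alone (median difference 185.5 bases, 22 higher). This list passed in none of the alternatives run for the lists. Other members of that list did not pass the limma test. BHLH39 had 534 bases in seedlings and 1902 in roots (limma, adjusted p = 0.25), and IRT1, the main root iron transporter, 303 and 1434 (limma, adjusted p = 0.166). No called gene was a member of the lists for root development, suberin, shoot development and stomata, the circadian clock, housekeeping, the DNA damage response, wounding and early stress, or seed and reproductive genes. Adjusted over the list alone, 1 gene of root development and 1 of suberin fell.

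Outside the lists, the genes named as higher in roots were covered in both root libraries and in neither sorted seedling library. They were AT1G19900 (1336 ± 247 bases), CYP708A2 (AT5G48000, 938 ± 339), AT3G45540 (877.5 ± 27.6), SVL3 (AT3G20520, 759 ± 232) and AT5G54790 (751.5 ± 141; SD, n = 2 each). Among the genes named as lower in roots, 4 lay in a cluster of small auxin up-regulated (SAUR) genes on chromosome 1, whose windows overlap. SAUR63 (AT1G29440) had 2292 ± 153 covered bases in seedlings, AT1G29430 2280 ± 170, AT1G29435 2232 ± 238 and AT1G29450 2119 ± 398 (SD, n = 2 each), and none of the 4 had a covered base in roots. AT1G29460, which shares the cluster, was called lower too. PKS4 (AT5G04190), a substrate of phytochrome kinase activity in light signalling, went from 2027 ± 341 bases to none. The adjusted p of the 20 named genes lay between 0.0195 and 0.0439 (limma). The called region over the SAUR63 cluster, joined over all libraries, spans chromosome 1 from 10299767 to 10309227, the one over RBCS2B and RBCS1B chromosome 5 from 15376136 to 15385749, and the one at BHLH38 chromosome 3 from 21085029 to 21086519 (TAIR10, per the submitters' processing notes).

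**Figure D1:**
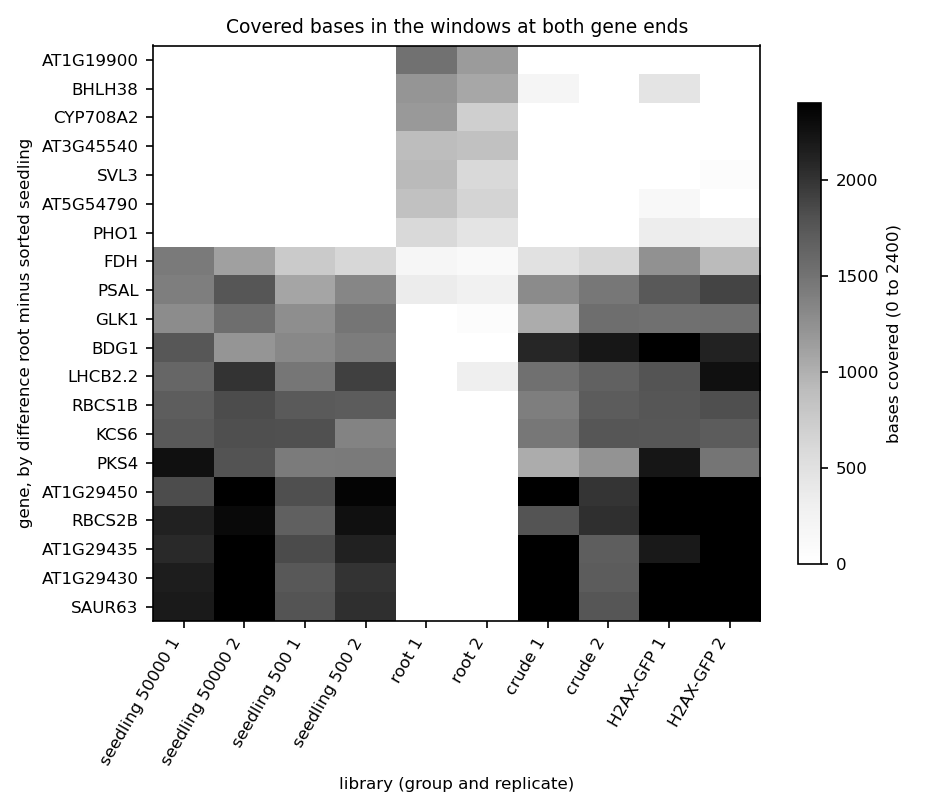
Covered bases (0 to 2400, grey scale) in the windows at both ends of the 20 genes named for root against sorted seedling, one row per gene from most to least root coverage relative to seedlings, one column per library. SAUR63, its 3 neighbours, RBCS2B, RBCS1B, KCS6, BDG1 and PKS4 are blank in both root libraries and covered in all 8 seedling libraries.

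In all, 163 of 23893 tested genes were called at an adjusted p under 0.05 with limma, 25 higher in roots (25 separate loci) and 138 lower (112 loci). That count depended on single libraries. It was 0 without either sorted seedling library of 50000 nuclei, without either library of 500 nuclei or without root replicate 1, 13 without root replicate 2, and 0 with only the 2 groups in the fit. Without root replicate 2, which covered 15.76 Mb against 21.56 Mb in replicate 1, all 13 were higher and none lower, so the balance of directions turned. No list passed in any of these 7 cases. Quantile normalization gave 106 higher and 163 lower, with the median over all genes at 27.2 instead of -83 bases, and division by covered length 24 higher and 22 lower, with the median at 10.54.

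Set against the mean of all 4 seedling groups, which brings in 8 seedling libraries, 11 photosynthesis genes fell and 3 nutrient uptake genes rose in roots. RBCS2B had 2124 covered bases on average over the 8 seedling libraries, BDG1 1813, RBCS1B 1704 and KCS6 1671, and none of them was covered in a root library. LHCB2.2 had 1778 over the seedling libraries and was covered in 1 of the 2 root libraries. FRO7 (AT5G49740), a ferric chelate reductase of the chloroplast, lies beside the called gene FRO6 and had 1906 bases in seedlings and none in roots. The cluster of SAUR63, AT1G29430, AT1G29435 and AT1G29450 had 2137 to 2200 bases over the seedling libraries. Higher in roots were BHLH38 with 1131 ± 98.3 bases against 82.1, PHO1 with 523 ± 103 against 82.6, and AKT1 (AT2G26650), a potassium channel of root cells, with 1629 ± 27.6 against 938 (SD, n = 2 root libraries each). The seedling mean of PHO1 came from H2AX-GFP seedlings alone, with 330.5 ± 4.9 bases (SD, n = 2), and no other seedling group had a covered base. AT1G19900, CYP708A2, AT3G45540, AT2G37120 (879 ± 455 bases) and PLP5 (AT4G37060, 729 ± 240, SD, n = 2) were covered in both root libraries and in none of the 8 others.

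In this contrast 11 of 45 photosynthesis genes fell (Fisher's exact test, adjusted p = 5.44e-10), 34 adjusted over the list alone. Of the cuticle list 3 of 15 fell (Fisher's exact test, adjusted p = 8.18e-03), 6 adjusted over the list alone, and of the nutrient uptake list 3 of 28 rose (Fisher's exact test, adjusted p = 6.92e-03), 9 adjusted over the list alone. Over 20 alternatives the photosynthesis list passed in 19, the cuticle list in 16 and the nutrient uptake list in 10. None of the 3 passed without root replicate 1. The nutrient uptake list was also lost without root replicate 2, either sorted seedling library, either library of 500 nuclei or crude replicate 2, with the 500 bp window, with the better-scoring 50% of regions and with a replicate block (Fisher's exact test, adjusted p = 0.0832). The cuticle list was also lost without sorted seedling replicate 1 or crude replicate 2 and with the 2000 bp window. The root development list had 1 call, WER, a regulator of epidermal cell fate, which had 799.5 ± 61.5 bases in sorted seedlings (SD, n = 2) and none in roots (limma, adjusted p = 0.0406 against all 4 groups). WER was chosen for mention after its values were seen. Adjusted over the list alone, root development had 3 higher and 1 lower, wounding and early stress 2 and 2, housekeeping 1 higher, and shoot development and DNA damage 1 lower each. The suberin, clock and seed lists had none. With limma, 481 genes were called, 144 higher in roots (117 loci) and 337 lower (253 loci). Without root replicate 1 the count was 0, without root replicate 2 it was 93 higher and 33 lower, and without either library of 500 nuclei 169. Without sorted seedling replicate 1 or 2 it was 295 or 191. Quantile normalization gave 532 higher and 569 lower, and division by covered length 403 and 428.

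**Figure D2:**
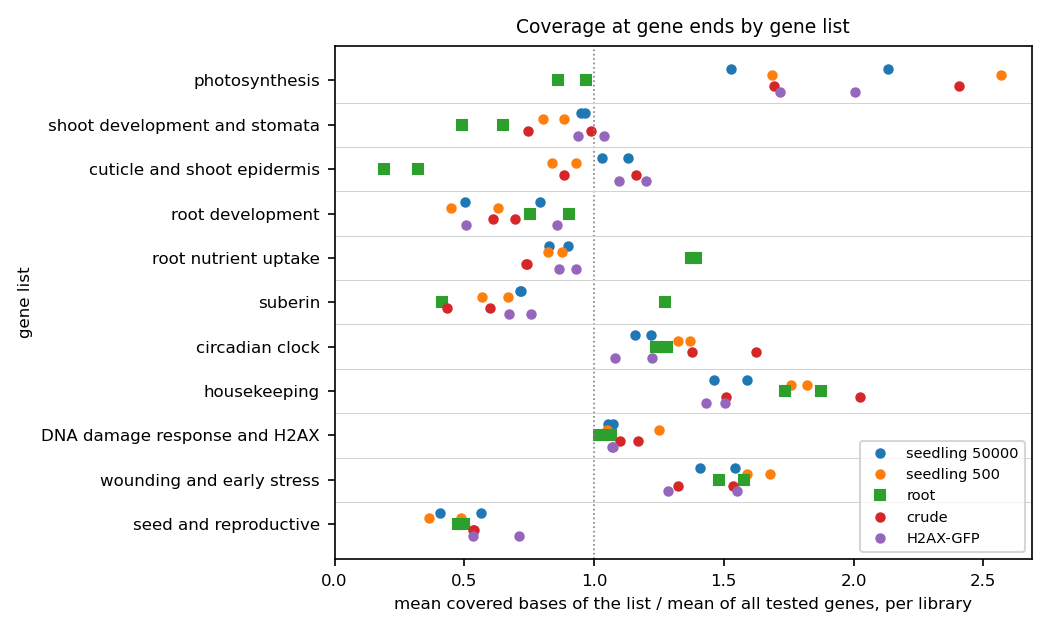
Mean covered bases of each gene list divided by the mean over all tested genes of the same library (horizontal axis, a ratio), one point per library, for the 11 lists. Root libraries (squares) sit between 0.863 and 0.969 for photosynthesis, where the 8 seedling libraries sit between 1.527 and 2.569, and at 1.375 and 1.392 for root nutrient uptake, where seedlings sit between 0.736 and 0.93.

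List means were also compared without a call per gene. Photosynthesis genes had 0.916 ± 0.075 times the mean coverage of all genes in roots (SD, n = 2) and 1.967 ± 0.377 in seedlings (SD, n = 8). Cuticle genes had 0.257 ± 0.092 and 1.034 ± 0.136, genes of shoot development and stomata 0.569 ± 0.111 and 0.914 ± 0.098, and nutrient uptake genes 1.384 ± 0.012 and 0.837 ± 0.07. For each of these 4 lists no other of the 45 choices of 2 libraries gave as large a difference (exact permutation test, two-sided, p = 0.0222, the smallest it can give). None passed once adjusted over 11 lists (exact permutation test, adjusted p = 0.061). With 4 lists at the smallest p, that adjusted p could not have been lower, so it does not speak against a difference. Root development genes had 0.83 ± 0.106 in roots and 0.63 ± 0.145 in seedlings (exact permutation p = 0.1333), and suberin genes 0.843 ± 0.608 and 0.642 ± 0.104 (exact permutation p = 0.3111). The other 5 lists had an exact permutation p of 0.2444 or more. This test was added after the data had been seen.

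By region, 1568 merged regions were called in both sorted seedling libraries and in neither root library, and 333 in both root libraries and in neither sorted seedling library. The total of 1901 compares with 854 for the division by replicate number and 331 for the crossed one. With the same number of regions per library the seedling-only and root-only regions numbered 1054 and 820. Regions missing from both root libraries and present in all 8 seedling libraries numbered 520, more than for any other of the 45 choices of 2 libraries (exact permutation p = 0.0222), the highest of which had 281. When 50% of a merged region had to be covered, the root pair had 256 and another choice 502 (exact permutation p = 0.0889), which ends this call. Regions in both root libraries and in no other numbered 160, and 4 of the 45 choices, the root pair included, had at least as many, up to 290 (exact permutation p = 0.0889). That p was 0.0222 with the same number of regions per library.

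Libraries from 500 sorted nuclei were compared with those from 50000 as the labels give nuclei number as the difference between them. The mean of each of the 11 lists lay below that of 50000 nuclei, though no gene passed the test. The mean over all tested genes was lower too, at 616 ± 72.6 bases against 873.5 ± 56.6 (SD, n = 2 each). Lower means were thus not particular to the lists. Photosynthesis genes were covered in 100% of cases in every library of both groups, with a mean of 1288 ± 230 bases from 500 nuclei and 1586 ± 269 from 50000 (SD, n = 2 each). Housekeeping genes, also covered in 100%, had 1102 ± 103 and 1331 ± 6.9 bases. Nutrient uptake genes had 524 ± 84.4 and 756 ± 95.0, and 64.5% ± 0 against 75.8% ± 2.3 of the 31 listed were covered (SD, n = 2 each). With limma, 0 of 23893 genes were called, 1778 had an unadjusted p under 0.05, and the median gene differed by -211.5 bases. Without any difference, a share of about 0.05 of the tested genes would have such a p, here and for crude nuclei and H2AX-GFP below. Counts by unadjusted p thus name no gene as different. No member of the 11 lists was called, and 1 suberin gene fell adjusted over the list alone. Both sorted seedling libraries and neither library of 500 nuclei held 808 merged regions, and the reverse held for 36. The same 4 libraries divided by replicate number gave a total of 1763 such regions, and the crossed division 108, against 844 for the real groups. The order of the first turned round when 50% of a merged region had to be covered, with 2038 by number and 2946 for the real groups.

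**Figure D3:**
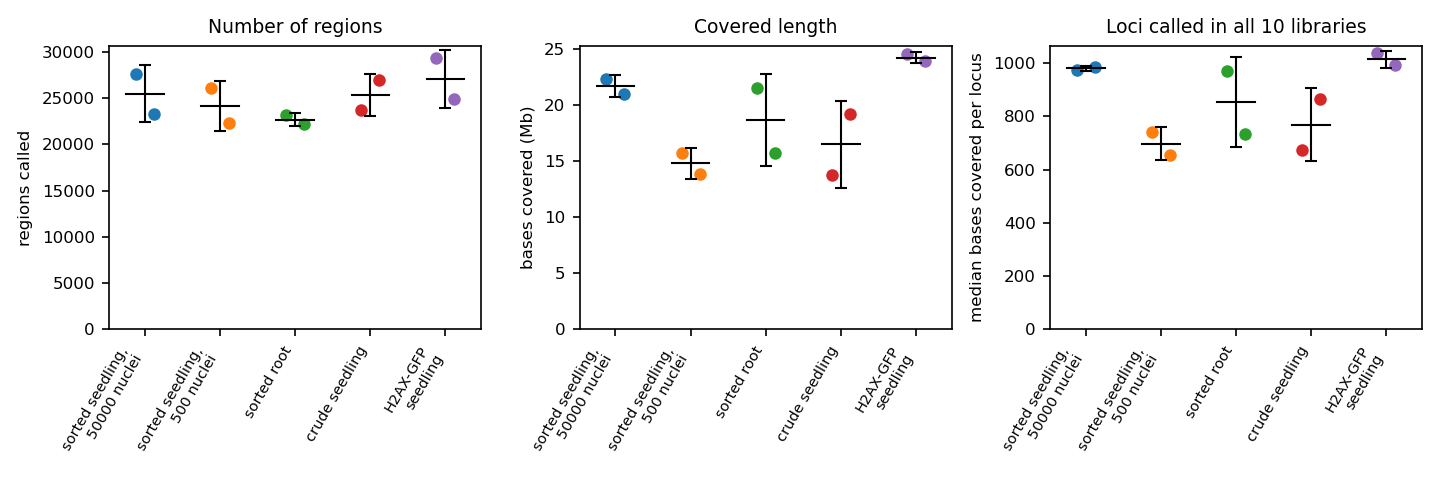
Number of regions called, covered length in Mb, and median bases covered at the 12394 merged regions called in all 10 libraries, one point per library, with group means (bars) and SD (error bars, n = 2). Both libraries of 500 nuclei and both crude libraries lie below both sorted seedling libraries of 50000 nuclei in the right panel, at 653 to 866 against 974.5 and 987 bases. Root replicate 2 lies below them too, at 735, and root replicate 1 only just, at 972.

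In covered length, the sorted seedling libraries of 50000 nuclei held 21.706 ± 0.974 Mb and those of 500 nuclei 14.819 ± 1.345 Mb (SD, n = 2 each), a gap larger than both SDs. The number of regions was 25468 ± 3061 and 24177 ± 2705, a gap within the SD. By replicate number it was 27632 and 26089 for replicate 1 and 23303 and 22264 for replicate 2, though the labels do not say that a number pairs libraries. With 2 libraries against 2, an exact permutation test cannot give a p under 0.33.

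Seedling nuclei labelled crude were compared with the sorted reference group. The mean of each of the 11 lists lay below that of sorted nuclei, though no gene passed the test. Over all tested genes the mean was lower too, at 686.9 ± 162.9 bases against 873.5 ± 56.6 (SD, n = 2 each). Photosynthesis genes, covered in 100% of cases in both groups, had 1368 ± 12.5 bases in crude and 1586 ± 269 in sorted libraries. Genes of wounding and early stress had 993 ± 335 and 1285 ± 0.3, and genes of the circadian clock 1016 ± 124 and 1038 ± 29.6 (SD, n = 2 each). With limma, 0 genes were called, 2264 had an unadjusted p under 0.05, and the median gene differed by -138 bases. With the better-scoring 50% of regions, 38 genes were called, 4 higher and 34 lower. No list member was called, and 1 suberin gene fell adjusted over the list alone. By region, 574 were in both sorted and neither crude library and 185 the reverse, while the division that paired unlike numbers gave a total of 1330 and that by replicate number 421, against 759 for the real groups. With the same number of regions per library the division of unlike numbers gave 649 against 879, and with 50% of a merged region covered the totals were 2016 and 2014. The crude libraries covered 16.522 ± 3.877 Mb. Crude replicate 1, with 13.78 Mb, had the lowest mean overlap with the other libraries, a Jaccard index (shared bases over bases in either) of 0.484.

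The 35S:H2AX-GFP line was compared with the wild type. HTA3 and HTA5, the genes for H2AX, had 1944 ± 645 and 1264 ± 43.1 covered bases in the transgenic line and 1661 ± 359 and 1214 ± 117 in the wild type (SD, n = 2 each), differences that did not pass (limma, adjusted p = 1 for both). Genes of the DNA damage response had 994 ± 107 bases against 929 ± 49.9, and photosynthesis genes 1717 ± 11.2 against 1586 ± 269 (SD, n = 2 each). All tested genes had a mean of 927.6 ± 96.2 against 873.5 ± 56.6 (SD, n = 2 each), so higher means were not particular to these lists. With limma, 0 genes were called, 759 had an unadjusted p under 0.05, and the median gene differed by 23.5 bases. Of the lists, shoot development and stomata had 1 gene that rose adjusted over the list alone, and no other list had any. The smallest adjusted p, 0.0925 with limma, was shared by AT1G47655, PRP1, NP2 and RLP23, chosen after their values were seen. PRP1 and its neighbour NP2 had 683 ± 18.4 and 659 ± 18.4 bases in the transgenic line (SD, n = 2) and no covered base in the 8 other libraries. Without H2AX-GFP replicate 1, 184 genes were called, all higher, with the better-scoring 50% of regions 27, and with the same number of regions per library 2. The line had 498 regions in both of its libraries and in neither wild-type one, and 50 the reverse, but 242 and 147 with the same number of regions per library. Division by replicate number gave a total of 2332 and the crossed division 237, against 548 for the real groups.

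**Figure D4:**
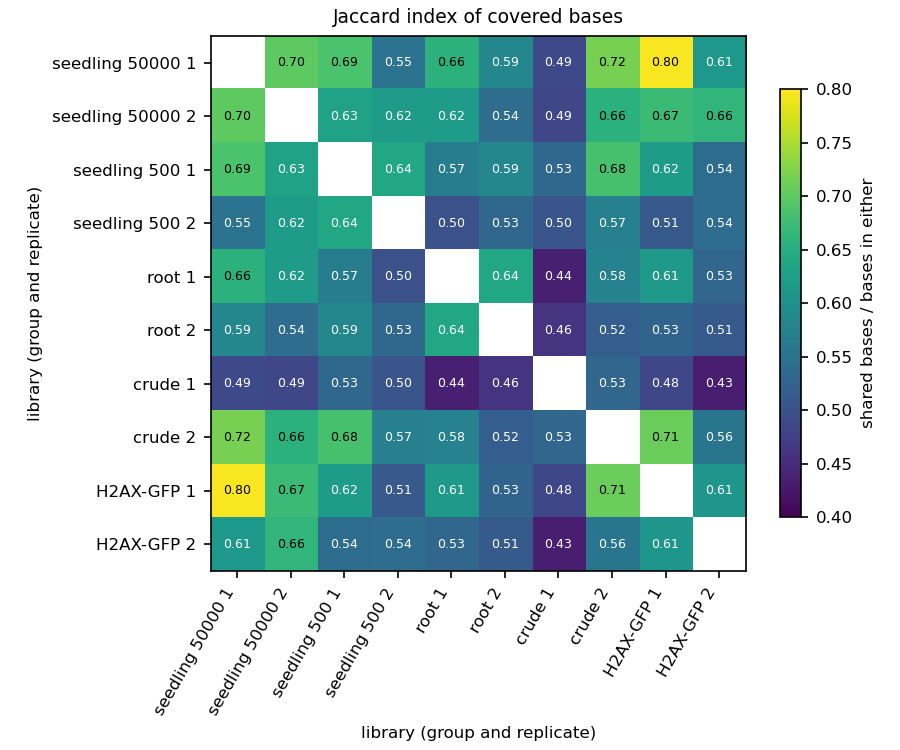
Jaccard index of covered bases for each pair of the 10 libraries (colour and number), rows and columns ordered by group. The highest value, 0.797, is between sorted seedling replicate 1 and H2AX-GFP replicate 1, and crude replicate 1 has low values throughout.

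Libraries of a group were compared with pairs drawn without regard to group. The mean Jaccard index was 0.7 for sorted seedlings, 0.64 for 500 nuclei, 0.638 for roots, 0.532 for crude nuclei and 0.61 for H2AX-GFP, an average of 0.624. Of all divisions of the 10 libraries into pairs, 24 gave as high an average (exact permutation test, one-sided, p = 0.0254), against a mean of 0.582, above which the crude pair did not lie. By the share of regions with 1 shared base the test did not pass (exact permutation p = 0.06667). Without the 2 root libraries, 21 divisions did (exact permutation p = 0.2). In total 29359 merged regions were found, of which 12394 (42.2%) were called in all 10 libraries and 4212 (14.3%) in 1.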

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

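The test of rRNA genes was chosen only after the result was seen. Many of the regions with the highest scores, a value that no comparison used except to rank regions, lay near annotated rRNA genes. Of the top 20 regions, those within 10 kb of an rRNA gene numbered 12 and 12 in sorted seedlings, 11 and 9 from 500 nuclei, 11 and 13 in roots, 12 and 12 in crude nuclei and 13 and 12 in H2AX-GFP seedlings. The single highest-scoring region was near an rRNA gene in all libraries but crude replicate 2. Of the 39 loci that the top regions formed, 9 were near rRNA genes, so the other loci are not covered by what follows. Of all regions of a library, 0.058% to 0.086% lay that near. A candidate explanation is that many rRNA gene copies are collapsed into few in the reference, so that reads pile up there, for the loci near these genes. The lowest count over the libraries, 9 of 20, belongs to the counts that raised the question, so it decides nothing for or against collapsed copies, and no copy number was measured. No biological explanation was tested.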

How the results depend on the processing

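The gene span and single gene end windows, and leaving out libraries outside a comparison, were chosen after the results were seen. For root against sorted seedlings, the 163 calls became 299 with windows of 500 bp outside to 100 bp inside, 47 with 2000 bp outside, 24 over gene spans with 1000 bp on each side and 567 with each gene end on its own. They became 482 with the better-scoring 50% of regions, 280 with equal numbers of regions, 269 after quantile normalization, 46 after division by covered length, 254 with plain eBayes and 0 with only the 2 groups. Leaving out a library in turn gave 0 to 205. Of the 3 lists that passed, 1 passed with the 500 bp window, 0 after division by covered length, 0 with only the 2 groups and 0 to 1 with a library left out. The 481 calls of root against the 4 seedling groups became 997 with each gene end on its own, 770 with the better-scoring 50%, 730 with equal numbers, 1101 after quantile normalization and 831 after division by covered length, and 0 to 520 with a library left out. The genes named for both root contrasts kept their direction in each alternative where they had a value. For a gene with no covered base on one side, most alternatives cannot turn the direction. These are division by covered length, fewer regions, a library left out, a replicate block and other filters or fits. Most of the named genes were of this kind, so their kept direction says little. Of the 20 genes named for root against sorted seedlings, 0 passed the threshold with only the 2 groups in the fit. Directions of HTA3 and HTA5 over the alternatives were not counted. A library left alone in its group is assumed to vary like the others.

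With the replicate number as a block, root against sorted seedlings gave 78 calls and 1 list passed, photosynthesis. The labels do not say that a number pairs libraries. Deviations by number correlated across genes by 0.51 between sorted seedlings and 500 nuclei, 0.39 between sorted seedlings and H2AX-GFP, 0.43 between 500 nuclei and H2AX-GFP and 0.30 between roots and H2AX-GFP. The other pairs of groups lay between -0.22 and 0.095. Libraries with a number in common thus shared deviations in some groups, and the block was not part of the fit reported.

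The 0 calls for 500 nuclei stood in every alternative. Those for crude nuclei became 38 with the better-scoring 50%. Those for H2AX-GFP became 27 with the better-scoring 50%, 2 with equal numbers, and 0 to 184 with a library left out. The exact permutation p of same-group similarity became 0.06667 for regions sharing 1 base and 0.2 without the root libraries. The p for regions in the root pair alone became 0.0222 with equal numbers and 0.0222 with the better-scoring 50%, and for regions missing from the root pair alone 0.0889 when 50% of a merged region had to be covered. Under that condition the regions that part the groups numbered 2946 for 500 nuclei, 2014 for crude nuclei and 823 for H2AX-GFP, and with the better-scoring 50% of regions 368 for 500 nuclei and 303 for H2AX-GFP. The mean ratio near gene ends, 2.304, became 1.976 by bases and 2.811 with a flank of 500 bp. The gene span ratio of crude replicate 1 went from 0.952 to 1.022 by bases, and the ratio elsewhere reached 1.001 to 1.009 in 4 libraries with that flank. Against the replicate number split (2038), the 2946 for 500 nuclei turned the order round. Without root replicate 2 the calls turned from mostly lower to mostly higher in both root contrasts (13 and 0, 93 and 33). The cause of these shifts was not tested. The motif test with its alternatives and the fit of 2 groups for root against 4 groups were not run.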

Other observations

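The genes and families in this paragraph were chosen only after the results were seen. In roots, neighbours of CYP708A2 in the gene cluster of thalianol synthesis, a triterpene pathway, were called higher too. AT5G47980 had 787.5 ± 34.6 covered bases in roots and 38.0 ± 53.7 in sorted seedlings, and CYP705A5 1552 ± 212 and 143 ± 202 (SD, n = 2 each). THAS1, the synthase of the cluster, had 1543.5 ± 791 and 535.5 ± 408 and did not pass (limma, adjusted p = 0.509). BEE3, a transcription factor of brassinosteroid response, had 1868 ± 49.5 bases in sorted seedlings and none in roots, and EXPA1, an expansin, 1978 ± 189.5 and 27.5 ± 38.9 (SD, n = 2 each). Both were called lower in roots. Against the 4 seedling groups, 19 of 78 SAUR genes at 11 loci were lower in roots and 2 higher (Fisher's exact test, adjusted p = 1.44e-16 over 55 families). After division by covered length 18 were lower. Against sorted seedlings alone 10 were lower, and 0 after that division. SAUR genes were not counted with a library left out, and the calls of both root contrasts depended on single libraries. Of 30 BBX genes 4 were lower, with an adjusted p of 0.0438 by Fisher's exact test. The set of families was narrowed after a first look, and this p passed 0.05 only after that, so it is no call. GMI1, a gene induced by DNA damage, was called in H2AX-GFP seedlings only with the better-scoring 50% of regions (limma, adjusted p = 0.0171, against 1 with all regions).

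Libraries of 500 nuclei and crude libraries covered less of the genome than both sorted seedling libraries of 50000 nuclei. With the same number of regions per library, the highest of the 4 lower libraries covered 18.06 Mb, below both sorted seedling ones at 20.8 and 20.823 Mb. Mean numbers of regions were already similar, at 25468 in sorted seedlings, 24177 from 500 nuclei and 25320 in crude nuclei. Equal numbers could thus change little. The values with and without equal numbers argue against the number of regions as the whole cause. Regions were also narrower at shared loci. At regions called in all 10 libraries the highest of the 4 covered a median of 866 bases, against 974.5 and 987. With similar numbers of regions, a lower covered length means narrower regions on average, so this largely restates the pattern and leaves its cause open. Root replicate 2, also of 50000 sorted nuclei, covered 15.764 Mb and a median of 735 bases, so low coverage and narrow regions were not particular to those 4 libraries. Depth per library is unknown and stays open, and no biological explanation was tested.

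More regions were in both sorted seedling libraries and no root library than the reverse. With equal numbers of regions the ratio was not 4.709 but 1.285 (95% exact binomial interval over regions, 1.172 to 1.41). This interval takes regions as independent and leaves out the spread between libraries, so it cannot decide the cause. The prediction set beforehand for a smaller number of root regions as the cause was a ratio under 1.2, and 1.285 did not meet it. The interval, which was not part of that prediction, includes 1.2, so that explanation stays open. With the better-scoring 50% of each library's regions, where numbers still differ, the ratio was 2.547. Whole seedlings contain roots, which may also play a part. Genes of the root lists kept 69.2% ± 32.7 of their root coverage in seedlings (SD, n = 67 genes), and those of the shoot lists 40.3% ± 32.8 of their seedling coverage in roots (n = 89), a gap of 28.9 points (permutation test over genes, one-sided, p = 1e-05, the smallest it can give). With equal numbers of regions the parts kept were 61.9% and 42.5% (permutation p = 0.00047). Tissue itself, named by the design, stays open too.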
